A study of Mus musculus with 2 samples.

How the data were processed

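Acetylation of histone H3 at lysine 9 (H3K9ac), a mark found at the promoters of active genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the forebrain of newborn mice (postnatal day 0). Both samples belonged to 1 group and were biological replicates made from pooled male and female animals; the labels give 15 mice for replicate 1 and no number for replicate 2. Library fragments were selected at 300 to 500 bp, per the labels.

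Peaks were called by the authors on the mm10 assembly from each replicate alone and from both alignments together, and a further deposited list holds the peaks termed replicated, per the file descriptions deposited with the samples. The peak caller, its version, its threshold and the aligner are not given in the sources used here. The signal values that the authors' peak caller gave each peak were used as deposited; what they are relative to is not given in the sources used here, so they served only to describe, rank and filter peaks. The deposited −log10 p and −log10 q values were used only as filters. The smallest −log10 p in each list lay just above 2, as in a list kept at p 0.01. Each replicated peak was identical in position and values to a peak of the pooled list, which showed that the replicated list (26861 peaks on the assembled chromosomes) was a subset of the pooled list (58425 peaks). Of the replicated peaks, 25205 (93.8%) overlapped the own lists of both replicates, 615 that of replicate 1 only, 1012 that of replicate 2 only and 29 neither. Read counts were not part of the files, so the sequencing depth of each replicate is unknown, and no value here carries an interval for it. The 2 files named as input were not used. Peaks on unplaced sequences (10 of the replicated list) and genes of chromosome Y were left out.

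Peaks on chromosomes 1 to 19, X and Y were kept. Genes and transcript starts (TSSs) came from GENCODE release M21 for GRCm38, the assembly behind mm10; chromosome lengths and sequence came from RefSeq GRCm38.p6. No peak ran past a chromosome's end. A peak was at a TSS when at least 1 bp of it lay within 1000 bp of any annotated transcript start of a protein-coding gene, and was otherwise distal. A gene had a TSS peak when a replicated peak met that condition at any of its starts. The 21755 protein-coding genes on chromosomes 1 to 19 and X had 93196 distinct starts. For each gene, the signal value was that of the strongest TSS peak in each replicate's own list, given as the mean ± SD of 2 replicates.

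Peaks of the replicates were compared by overlap of at least 1 bp. Overlap and location were tested one-sided with a permutation test of 1000 circular shifts of the peaks within each chromosome, whose smallest p is 0.001. Signal values were compared with Spearman's rho across regions; regions are not independent replicates, so no p was computed. Gene lists fixed before the data were examined (28 lists) were tested with Fisher's exact test, two-sided, against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 28 lists and a threshold of 0.05. Genes are not independent replicates, and neighbouring members of a cluster can share a peak, so these tests describe the deposited lists and not variation among animals. Shares of genes are given with 95% Wilson intervals, which cover only the number of genes counted. Acetylated domains were measured as the bp of replicated peaks within 5000 bp of the start with most coverage; the widest 5% of genes with a TSS peak were tested in the same way, over lists with at least 3 members that had a TSS peak. With 2 replicates of 1 group, no comparison between groups exists, and values per replicate are given as mean ± SD without a test.

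Named genes followed a rule fixed at the same time: per list, the 3 members with a TSS peak of highest mean signal value, and the members that went against the majority of the list where these were 5 or fewer; the 10 genes at the strongest replicated TSS peaks; the 10 genes with the widest domains; the 5 strongest distal replicated peaks; and the 5 strongest peaks of each replicate that the other lacked. Not all of them are printed. Members of a list that were among the widest domains are named as further examples. 1 fixed name, Ahsp, was not found in the annotation.

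Alternatives covered the overlap that counts as shared, stricter −log10 q values (2 and 5), the 20000 strongest peaks of each list, TSS windows of 500 and 2000 bp, the gene's 5′ end alone, each replicate's own list, the pooled list, a background without chemosensory receptor genes, 3 strata of promoter CpG content (observed over expected CpG within 500 bp of the gene's 5′ end; conditional exact Mantel-Haenszel test), the widest 10% of domains, and domains taken as the widest single peak. Added after the data were seen were protein-coding transcripts of GENCODE's basic set, leaving out starts within 2000 bp of another gene's start, and domain tests in strata of CpG content, number of starts or signal value.

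Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The overlap counts were checked against bedtools 2.31.1, and 0 of 8 differed by over 0.1%. On simulated data, 4 of 100 pairs of independent lists and 100 of 100 pairs sharing 5% of their peaks gave a shift p below 0.05. In simulated gene lists of the real sizes, the Fisher test called 93.6% of lists set to a share of 95%, 80.6% of lists set to 25% and 1.39% of lists left at the share of all genes. The simulated peaks were placed evenly and the simulated genes drawn independently of each other. The simulations therefore do not cover clustered peaks, peaks shared by genes or the dependence on CpG content. Conditional 95% intervals of odds ratios within CpG strata, added after the data were seen, came from R. In 0 of 20 simulated tables did the p of the stratified test differ from that of R 4.3.3 by over 0.1%. Figures were drawn with matplotlib 3.10.9.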

Results

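H3K9ac was profiled in forebrain from newborn mice in 2 biological replicates of pooled animals. The lists held 51434 peaks for replicate 1, 43931 for replicate 2, 58425 for both alignments pooled and 26861 replicated peaks on chromosomes 1 to 19, X and Y. Peaks of the single replicates were short, with a median width of 319 bp in replicate 1 and 409 bp in replicate 2. Those of the replicated list had a median width of 995 bp. The 4 lists covered 32.3, 33.3, 42.8 and 33.8 Mb, respectively. The sequencing depth is unknown, and the design has no second tissue, age or treatment, so the comparisons are between the replicates, between kinds of genomic region and between groups of genes.

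The first question was how far the acetylated regions of the replicates were the same. Strong peaks were shared and weak ones mostly were not. Of the replicate 1 peaks, 58.9% overlapped a replicate 2 peak, and of the replicate 2 peaks, 63.8% overlapped a replicate 1 peak. Shifted peaks gave means of 2.28% and 2.59%, and none of the 1000 shifts reached the observed value in either direction (permutation test, one-sided, p = 0.001, the smallest possible). Among peaks with a −log10 q of at least 5 in both lists, the observed shares were 93.4% and 86.0%. A reciprocal overlap of at least 50% was met by 21323 peaks of each full list. Of the bases covered in either replicate, 59.9% were covered in both, against 0.676% for shifted peaks (permutation test, p = 0.001). In the strongest 10% of each list by signal value, 100% of the peaks were shared. In the weakest 10% the shares were 22.3% for replicate 1 and 26.6% for replicate 2. Over the 25666 regions called in both, the signal values of the replicates had a Spearman's rho of 0.927. It was 0.941 over the 15953 shared regions at a TSS and 0.672 over the 9713 distal ones. These are correlations across regions, which are not independent replicates. The log2 ratio of replicate 2 to replicate 1 had an SD of 0.315 at a TSS and 0.365 in distal regions. Median signal values in replicates 1 and 2 were 10.9 and 11.9 at a TSS, against 3.88 and 4.00 in distal regions. The lower distal rho alone is therefore no measure of how far the values differed.

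**Figure D1:**
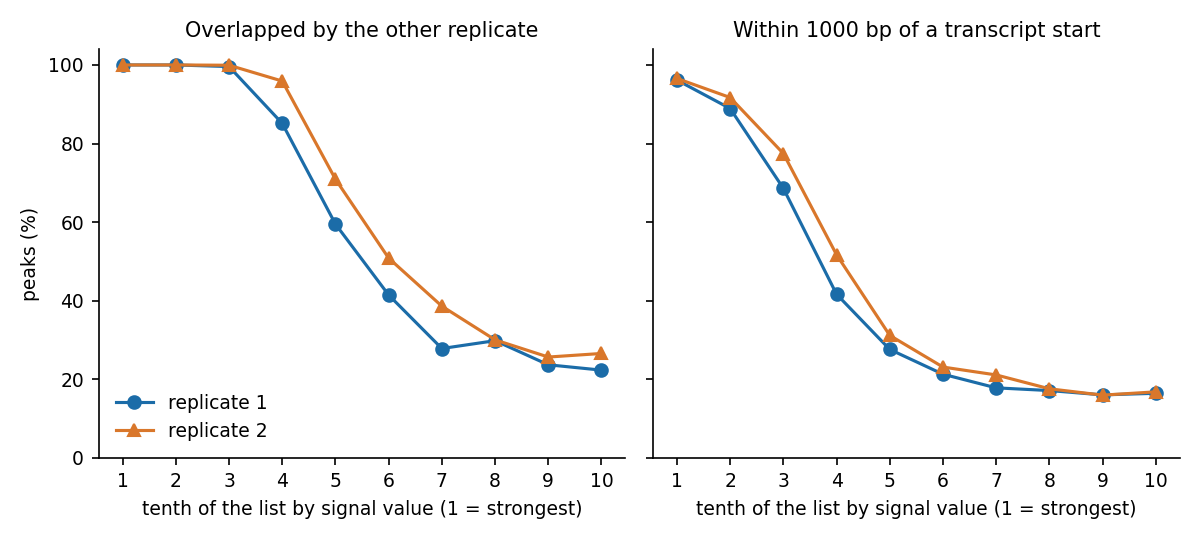
Percentage of peaks (y axis) in each of 10 equal parts of a replicate's list ranked by signal value (x axis, 1 = strongest), for replicate 1 (circles) and replicate 2 (triangles): peaks overlapped by the other replicate (left) and peaks within 1000 bp of a transcript start (right). Both shares fell with signal value, from 100% to 22.3% (replicate 1) and 26.6% (replicate 2) on the left.

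Peaks that only 1 replicate had were weak and mostly away from promoters. Replicate 1 had 21123 of them, with a median signal value of 3.08 against 5.61 for its shared peaks. Replicate 2 had 15883, with 3.14 against 6.34. At a TSS lay 12.9% of these peaks in replicate 1 and 15.2% in replicate 2 (mean 14.1 ± 1.63%, SD, n = 2), compared with 60.9% and 60.8% of the shared peaks. The mean was 28.8% among peaks with a −log10 q of at least 5, 6.06% at gene 5′ ends alone and 23.5% with a window of 2000 bp. The strongest peak that replicate 2 lacked had a signal value of 6.18 and lay in an intron of Dync1li2, which encodes a dynein light intermediate chain, on chromosome 8 from 104436229 to 104436790. The strongest peak that replicate 1 lacked had a signal value of 8.28 and lay on chromosome 3 from 93554381 to 93554945, 135 bp from a transcript start of S100a10, a calcium-binding protein gene.

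The second question was where in the genome the acetylated regions lay. H3K9ac was concentrated at the starts of protein-coding genes. Of the replicated peaks, 59.6% were at a TSS (95% interval 59.0 to 60.2%), compared with a mean of 5.96% for shifted peaks (permutation test, p = 0.001), and they held 75.6% of the covered bases. By the position of the summit, a further 2.97% were in exons, 16.9% in introns and 20.5% between genes. In the replicates' own lists, 41.2% and 44.3% of the peaks were at a TSS, and in the pooled list, of which the replicated list is a subset, 35.1%, with 62.7% of the covered bases. Peaks at a TSS were stronger and wider than distal ones in both replicates. The ratio of median signal values was 2.68 ± 0.259 (SD, n = 2), from medians of 8.83 ± 1.06 and 3.29 ± 0.0792. The ratio of median widths was 3.55 ± 0.122 (SD, n = 2), from medians of 938 ± 130 bp and 263.5 ± 27.6 bp. The width ratio was 1.85 among peaks with a −log10 q of at least 5 and 2.35 in the replicated list.

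A replicated TSS peak was found at 13815 of the 21755 protein-coding genes, or 63.5% (95% interval 62.9 to 64.1%). The replicates' own lists gave 14106 and 14104 genes, of which 13775 were the same. The highest signal value of the replicated list was 48.4, at Srsf6, a splicing factor gene, on chromosome 2 from 162930532 to 162933028 (42.1 over the single replicates). Among the replicated peaks at a TSS, it was followed by Marcksl1 (47.1), which encodes a substrate of protein kinase C that binds actin, and by Rbm39 (45.0), another splicing regulator. Also among the 10 were Tnpo1, the nuclear import receptor transportin, with 44.8, Sp3, a transcription factor, with 43.4, and Mdm2, the ubiquitin ligase of p53, with 43.2. The list was completed by Usp22, Marcks, the actin gene Actg1 and the tubulin gene Tuba1a, whose peak is shared with the overlapping gene model Gm49450.

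The third question was which gene groups carried the mark. Of the 28 gene lists, 23 differed from other genes after adjustment: 11 had TSS peaks more often and 12 less often. Lists of telencephalic regulators and of forebrain neurons had a peak at all or nearly all genes, as did lists of genes that every cell uses. A TSS peak was present at 25 of 25 telencephalic transcription factor genes (100%, 95% interval 86.7 to 100%; Fisher's exact test, adjusted p = 4.53e-05). The highest signal values among them were those of Foxg1, a master regulator of telencephalon development, with 26.9 ± 0.126 (SD, n = 2), Bcl11a with 24.2 ± 1.94 and Pou3f3 with 23.4 ± 0.773. Foxg1 lies on chromosome 12 from 49382660 to 49386861, and the replicated peak over its start was 14083 bp wide and shared with the overlapping gene model Gm43517. All 24 genes of cortical excitatory neurons had a TSS peak (adjusted p = 4.53e-05, Fisher's exact test), with the highest values at Lmo4 (22.1 ± 3), Nfib (22.0 ± 0.494) and Bcl11b (19.6 ± 2.16). So did all 30 neuronal and synaptic genes (adjusted p = 9.03e-06, Fisher's exact test), led by Vamp2, the synaptic vesicle protein synaptobrevin, with 34.8 ± 4.47, the adhesion molecule Ncam1 with 25.8 ± 1.15 and the neuronal tubulin Tubb3 with 24.8 ± 1.82.

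Genes of inhibitory neurons and of dividing progenitors were acetylated as well. Of 25 genes of GABAergic and striatal neurons, 24 had a TSS peak (adjusted p = 0.000382, Fisher's exact test). Dlx6, Dlx5 and Gad1, which encodes a GABA-synthesizing enzyme, had values of 15.6 ± 0.138, 13.7 ± 0.198 and 13.6 ± 0.526. The exception was Sst, the gene of the neuropeptide somatostatin, for which replicate 1 alone had a peak, with a signal value of 3.88. All 20 neural progenitor genes had a TSS peak (adjusted p = 0.000333, Fisher's exact test), with Msi1, an RNA-binding protein of neural stem cells, at 28.8 ± 0.0586. Of 24 cell cycle genes, 23 had one (adjusted p = 0.000607, Fisher's exact test), led by the mitotic kinase gene Aurka (16.8 ± 0.463, at a peak shared with Cstf1). The exception was the replication gene Mcm3, with a peak in replicate 1 alone (3.56). All 20 immediate early genes, which respond within minutes to neuronal activity, had a TSS peak (adjusted p = 0.000333, Fisher's exact test), with 24.4 ± 2.13 at Jund and 23.6 ± 2.35 at Dusp1. Within strata of promoter CpG content these 3 lists, GABAergic, cell cycle and immediate early, were no longer past the threshold (adjusted p = 0.0604, 0.700 and 0.0518, conditional exact Mantel-Haenszel test). The odds ratio of the GABAergic list went from 13.8 to 5.50 by the Mantel-Haenszel estimate and 7.85 by the conditional one (95% interval 0.975 to 413). That of the cell cycle list went from 13.2 to 1.93 and 2.11 (0.2998 to 92.5). The immediate early list stayed at 20 of 20, where the strata gave 17.5 expected genes and all genes 12.7.

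In 3 further lists, every gene had a TSS peak. TSS peaks were found at 76 of 76 cytosolic ribosomal protein genes (adjusted p = 2.57e-14, Fisher's exact test), at 58 of 58 respiratory chain genes (adjusted p = 2.84e-11, Fisher's exact test) and at 28 of 28 genes of histone acetyltransferases and deacetylases (adjusted p = 1.23e-05, Fisher's exact test). The highest values were 32.9 ± 3.99 (SD, n = 2) at Rps19, 25.7 ± 0.954 at Ndufa6 and 32.4 ± 1.89 at Ep300, which encodes the acetyltransferase p300. Imprinted genes had a peak at 21 of 24 (87.5%; adjusted p = 0.0214, Fisher's exact test), led by Ube3a with 23.6 ± 4.16. Igf2, Ndn and Rtl1 had none within 1000 bp of a start. For Igf2, replicate 1 alone had a peak (3.23). Ndn had 1357 bp of replicated peaks within 5000 bp of a start, and Igf2 and Rtl1 had 0 bp. With a window of 2000 bp, 22 of 24 imprinted genes had a peak. The call for imprinted genes was lost with starts near another gene left out (15 of 22, 68.2%) and with the gene's 5′ end alone (75%). It was also lost against a background without chemosensory receptors, where the share itself stayed at 87.5% (adjusted p = 0.0558, Fisher's exact test).

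**Figure D2:**
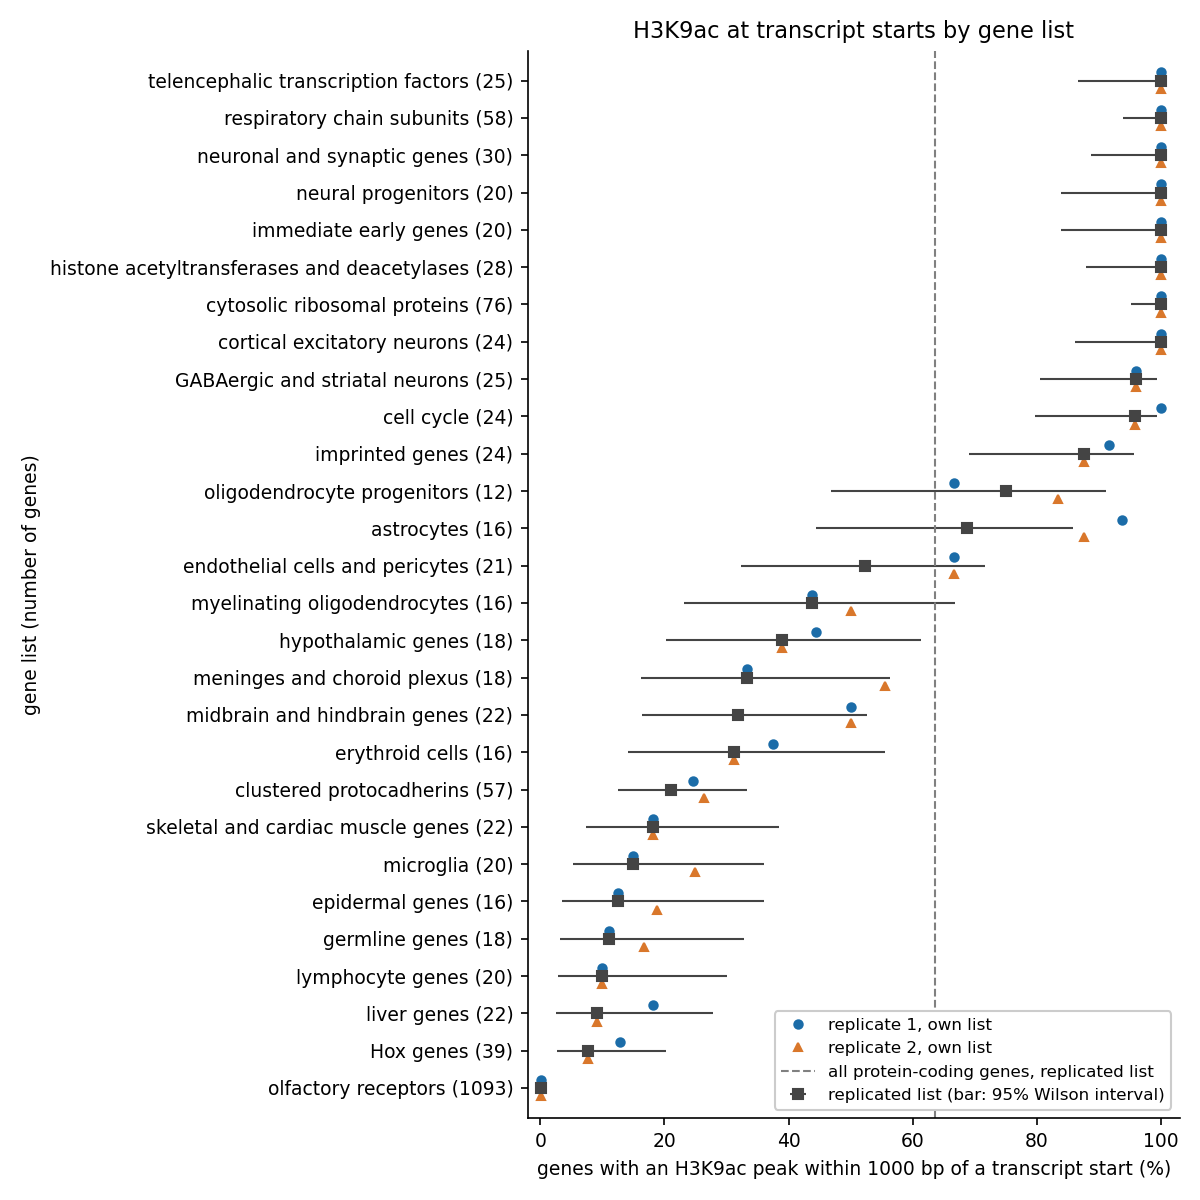
Percentage of genes with an H3K9ac peak within 1000 bp of a transcript start (x axis) for 28 gene lists (y axis, number of genes in parentheses). Squares with 95% Wilson intervals show the replicated list, circles and triangles the own lists of replicates 1 and 2, and the dashed line the 63.5% of all protein-coding genes. Lists of forebrain neurons and housekeeping genes sit near 100%, and olfactory receptors at 0.0915%.

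Genes of other tissues and of other body axes were mostly unmarked. Liver genes had a TSS peak at 2 of 22 (9.09%; adjusted p = 7.97e-07, Fisher's exact test), lymphocyte genes at 2 of 20 (adjusted p = 4.25e-06, Fisher's exact test) and germline genes at 2 of 18 (adjusted p = 1.82e-05, Fisher's exact test). Muscle genes had one at 4 of 22 (adjusted p = 4.11e-05, Fisher's exact test) and epidermal genes at 2 of 16 (adjusted p = 7.21e-05, Fisher's exact test). Of 1093 olfactory receptor genes, 1 had a TSS peak, Olfr94 (6.25 ± 0.760); the Fisher's exact p was too small for the software to represent. Several of the exceptions lay at a start shared with a neighbour. The peak counted for Apoh, a plasma glycoprotein gene (16.2 ± 0.211), also covered a start of Prkca, that for Foxa3 (15.7 ± 1.20) lay at Sympk, that for Foxp3 (13.1 ± 1.64) at Ppp1r3f, that for Gdf9 (14.0 ± 0.710) at Uqcrq and that for Mylpf (14.6 ± 1.01) at Tbc1d10b. For Krt1 (14.5 ± 2.17), Dazl (11.5 ± 3.07) and Lck (8.98 ± 0.788), no start of another protein-coding or long noncoding gene was at the peak. The peaks of Krt1 and Lck were at neither the gene's 5′ end nor the start of a basic transcript, whereas that of Dazl was at both. Liver genes had a peak at 4 of 22 in the own list of replicate 1 and in the pooled list and at 0 of 21 with starts near another gene left out, and muscle genes at 2 of 22 there and with a window of 500 bp. Epidermal genes had one at 0 of 16 with the gene's 5′ end alone, lymphocyte genes at 0 of 20 with basic transcripts, germline genes at 3 of 18 in the own list of replicate 2 and 1 of 18 with basic transcripts, and olfactory receptors at 0 to 2 over the alternatives. Within CpG strata, the lymphocyte and epidermal lists were no longer past the threshold (adjusted p = 0.0518 and 0.216, conditional exact Mantel-Haenszel test). The odds ratio of the lymphocyte list went from 0.0637 to 0.236 by the Mantel-Haenszel estimate and 0.174 by the conditional one (95% interval 0.0159 to 0.99994). That of the epidermal list went from 0.0820 to 0.163 and 0.260 (0.0219 to 1.63).

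Hox genes, which pattern the body axis behind the forebrain, had a TSS peak at 3 of 39 (7.69%; adjusted p = 3.81e-12, Fisher's exact test). These were Hoxa7 (8.91 ± 1.14), Hoxb13 (3.62 ± 0.542) and Hoxc6, for which the replicated peak had a counterpart at the TSS in replicate 1 alone (2.78). The own list of replicate 1 and the pooled list gave 5 of 39, and basic transcripts 1 of 39. Midbrain and hindbrain genes had one at 7 of 22 (31.8%; adjusted p = 0.00440, Fisher's exact test), with the highest values at Mafb (9.61 ± 2.16), Pitx3 (8.48 ± 3.10) and Egr2 (7.21 ± 0.707). In the pooled list 72.7% of these genes had a peak, more than among all genes and not past the threshold. Each replicate's own list gave 50%, also not past it. The strongest replicated TSS peak of Pitx3 lay on chromosome 19 from 46135495 to 46136735. This is at the 3′ end of the gene, which runs from 46135685 to 46148326 on the minus strand. Pitx3 was also scored as having a peak at its 5′ end. Within CpG strata the midbrain and hindbrain list kept its call. Its odds ratio went from 0.268 to 0.103 by the Mantel-Haenszel estimate and 0.0472 by the conditional one (95% interval 0.0130 to 0.161). Clustered protocadherins, whose variable exons each have their own promoter and are chosen by single neurons, had a peak at 12 of 57 (21.1%; adjusted p = 4.09e-10, Fisher's exact test), and at 19 of 57 in the pooled list. The highest values were at Pcdhac2 (19.1 ± 2.31), Pcdhgc3 (14.1 ± 1.02) and Pcdhgc4 (9.70 ± 1.53), which belong to the C-type members of the clusters.

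**Figure D3:**
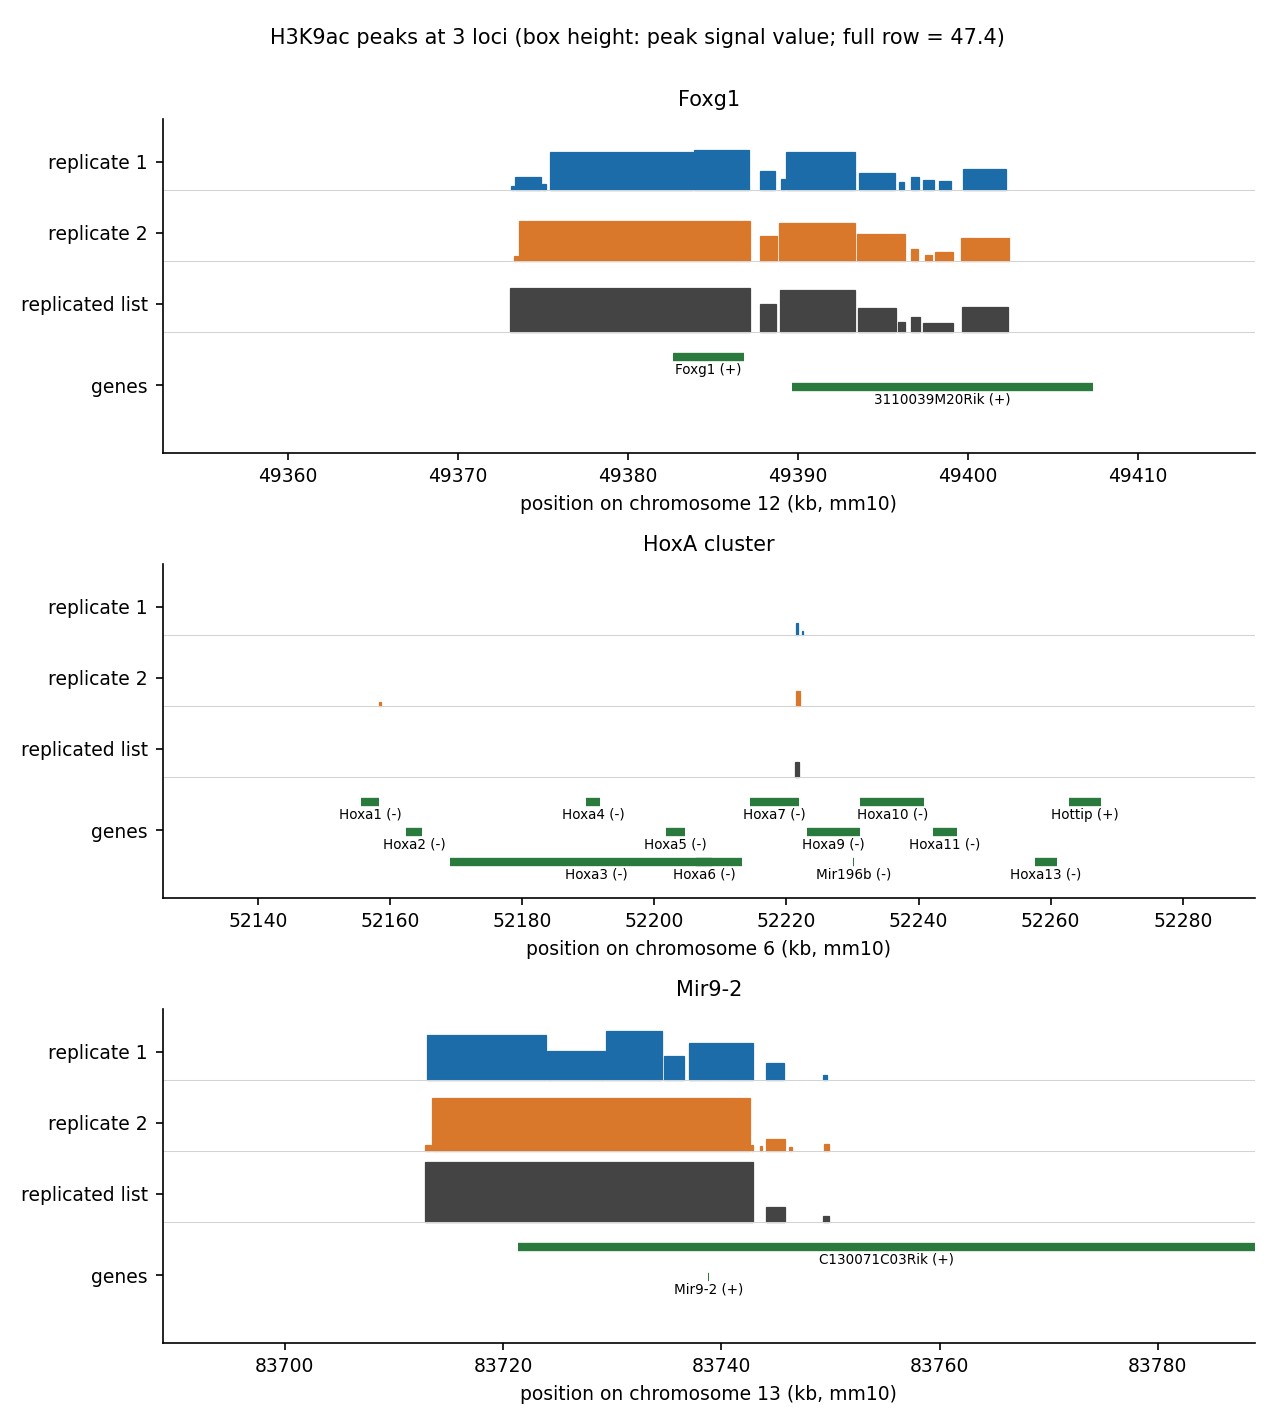
H3K9ac peaks at Foxg1 (top), the HoxA cluster (middle) and Mir9-2 (bottom) on mm10, with position in kb on the x axis and rows for replicate 1, replicate 2, the replicated list and annotated genes with their strand. Boxes span the peaks and their height is the signal value, a full row being 47.4; unnamed gene models are left out. In the replicated list, Foxg1 lies under a 14083 bp peak, the HoxA region holds 1 peak, and Mir9-2 lies in a peak of 30044 bp. Replicate 1 has shorter peaks at Foxg1 and Mir9-2.

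Genes of immune, membrane and blood cells gave low shares. Microglial genes had a TSS peak at 3 of 20 (15.0%; adjusted p = 2.94e-05, Fisher's exact test): Hexb, a lysosomal enzyme gene (10.6 ± 0.445), Irf8 (5.29 ± 0.180) and Sall1. The signal values of Sall1 differed between the replicates, 3.30 and 11.7. In the own list of replicate 2, 5 of 20 microglial genes had a peak. Genes of meninges and choroid plexus had one at 6 of 18 (33.3%; adjusted p = 0.0163, Fisher's exact test), with 14.0 ± 1.65 at Igfbp2. Erythroid genes had one at 5 of 16 (31.3%; adjusted p = 0.0203, Fisher's exact test), with 6.21 ± 0.101 at Klf1. Within CpG strata the microglial list was no longer past the threshold, with an odds ratio of 0.101 before and, within strata, a Mantel-Haenszel estimate of 0.0846 and a conditional estimate of 0.175 (95% interval 0.0152 to 1.23). Of its 20 genes, 16 were in the lowest stratum, and the strata gave 5.85 expected genes with a peak, against 12.7 from all genes. The erythroid list turned from an odds ratio of 0.261 to 1.76 by the Mantel-Haenszel estimate and 1.71 by the conditional one (95% interval 0.355 to 6.23). It also lost its call in the pooled list (7 of 16) and with starts near another gene left out (5 of 16), and had a peak at 3 of 16 genes at a −log10 q of at least 5. The list of meninges and choroid plexus lost its call in the own list of replicate 2 and in the pooled list (10 of 18 in each) and with starts near another gene left out (6 of 18).

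The remaining 5 lists were not past the threshold. Oligodendrocyte progenitor genes had a TSS peak at 9 of 12, with 10.9 ± 1.18 (SD, n = 2) at Vcan, and lacked one at Cspg4, Gpr17 and Neu4. Genes of myelinating oligodendrocytes had one at 7 of 16 and were past the threshold with a window of 500 bp (6 of 16). Their highest values were 14.7 ± 0.649 at Tspan2 and 13.5 ± 4.32 at Mbp, the gene of myelin basic protein. The Mbp peak was at the gene's 5′ end, on chromosome 18 from 82474737 to 82476341, and the gene runs to 82585637. That peak does not speak for starts elsewhere in Mbp. Astrocyte genes had a TSS peak at 11 of 16, with 14.9 ± 1.91 at the glutamate transporter gene Slc1a2. Of the 5 astrocyte genes without a replicated TSS peak, Gfap (3.03 ± 0.165), Aldh1l1 (3.06 ± 0.696) and Mlc1 (3.01 ± 0.146) had a weak peak in each replicate's own list, Aldoc in replicate 1 alone and S100b in neither. In the own list of replicate 1 and in the pooled list, 93.8% of the astrocyte genes had a peak, which was past the threshold. Endothelial and pericyte genes had one at 11 of 21, with 6.16 ± 1.39 at Sox18. Hypothalamic genes had one at 7 of 18 (38.9%, odds ratio 0.365; adjusted p = 0.0545, Fisher's exact test). They were past the threshold, with a peak less often than other genes, under 6 alternatives: a window of 500 bp, the gene's 5′ end alone and a −log10 q of at least 5 (6 of 18 in each), the own list of replicate 2, a background without chemosensory receptors, and CpG strata. Within CpG strata the odds ratio was 0.269 by the Mantel-Haenszel estimate and 0.146 by the conditional one (95% interval 0.0367 to 0.540). The highest value among the hypothalamic genes, 31.8 ± 1.95 at Agrp, was at a peak that also covered a start of Ctcf.

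The last question was where acetylation spread over wide domains. Of the 23 lists tested, telencephalic transcription factors had the largest share of genes among the widest domains. Among the 13815 genes with a TSS peak, the median covered length within 5000 bp of the start was 1905 bp, and the 691 genes of the widest 5% had at least 4430 bp. Of the telencephalic transcription factors, 24 of 25 were among these 691 (96.0%, 95% interval 80.5 to 99.3%; odds ratio 472, adjusted p = 2.25e-29, Fisher's exact test). Without replicate 2 they were 23 of 25 (odds ratio 226) and with the gene's 5′ end alone 19 of 24 (odds ratio 74.3), the lowest of the alternatives, while strata of signal value gave the highest odds ratio, 1240. Of the cortical excitatory neuron genes, 16 of 24 were (adjusted p = 7.54e-15, Fisher's exact test), among them Neurod2, Neurod6, Tbr1 and Satb2. Of the genes of GABAergic and striatal neurons, 10 of 24 were (adjusted p = 7.30e-07, Fisher's exact test), among them Dlx1, Dlx2, Gad1 and Gad2. Some genes are in more than 1 of these lists. Neural progenitor genes followed with 7 of 20 (adjusted p = 0.000191, Fisher's exact test), immediate early genes with 5 of 20 (adjusted p = 0.00979, Fisher's exact test) and neuronal and synaptic genes with 7 of 30 (adjusted p = 0.00259, Fisher's exact test). The other 17 lists were not past the threshold. Of these, the oligodendrocyte progenitor list (2 of 9) gained a call with the gene's 5′ end alone (3 of 7), basic transcripts (3 of 9), the pooled list (3 of 10) and strata of signal value (2 of 9), and the imprinted list gained one at a −log10 q of at least 5 (5 of 20). Cytosolic ribosomal protein genes had 6 of 76 among the widest and respiratory chain genes 0 of 58, although all of them had a TSS peak. With the pooled list, 9 of 76 ribosomal protein genes were among the widest (odds ratio 2.57), which was past the threshold. The progenitor and immediate early lists lost their call when domains were taken as the widest single peak. There the progenitor list still had an odds ratio of at least 4.77 (adjusted p = 0.0607, Fisher's exact test). The neuronal and synaptic list lost its call with the gene's 5′ end alone, where 4 of 27 were among the widest.

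The whole window of 10001 bp was covered at Bcl11a, Kdm6b, Nfib and Tnrc18. The next were Dlx1 (9912 bp), Meis2 (9912 bp), Nr2f1 (9904 bp), Islr2 (9886 bp), Pou3f3 (9781 bp) and Tcf4 (9738 bp). Of these 10, Bcl11a, Nfib, Dlx1, Meis2, Nr2f1, Pou3f3 and Tcf4 encode transcription factors, and Kdm6b encodes a demethylase of histone H3 lysine 27.

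**Figure D4:**
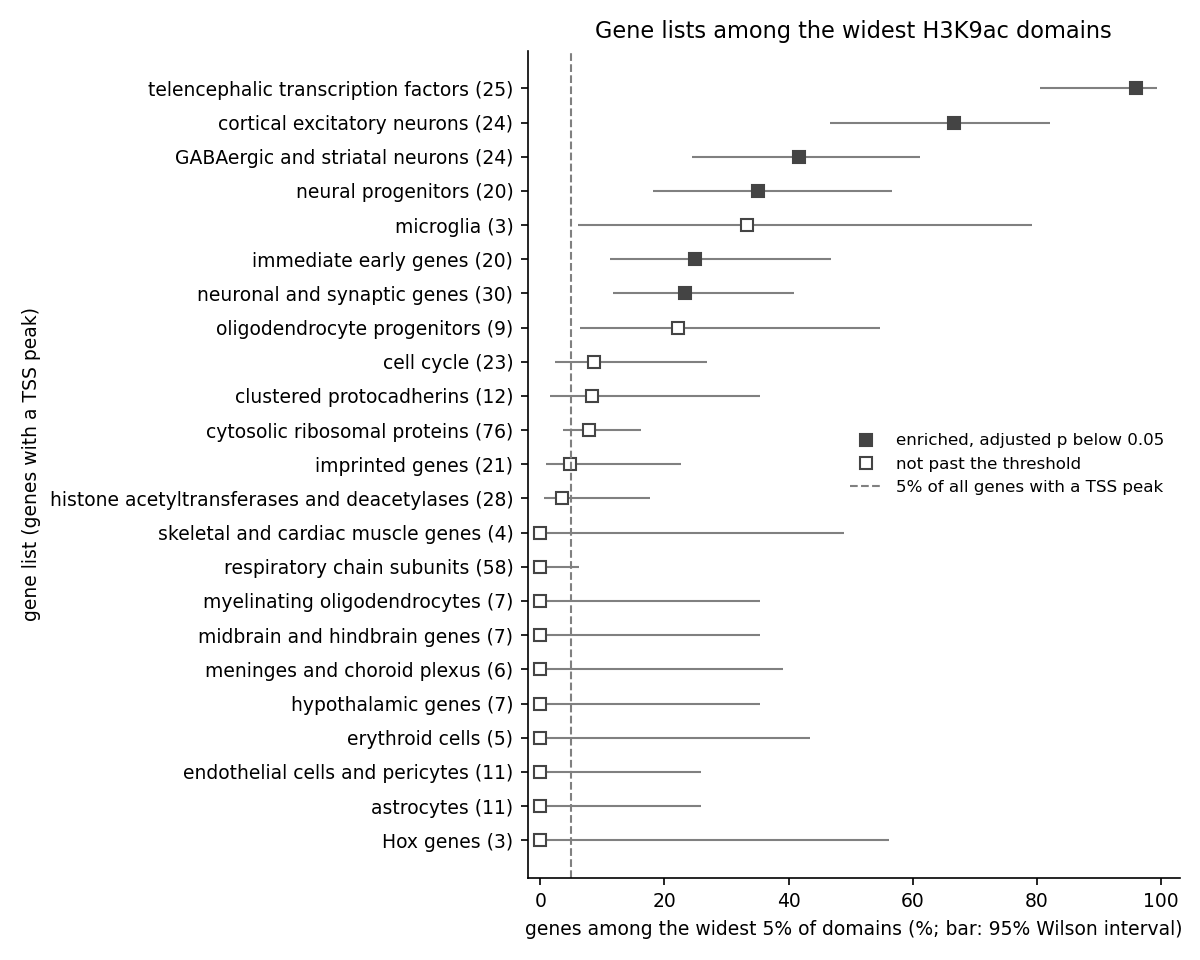
Percentage of genes with a TSS peak that are among the widest 5% of H3K9ac domains (x axis, with 95% Wilson intervals) for 23 gene lists (y axis, number of genes with a TSS peak in parentheses). Filled squares are lists past the adjusted threshold, and the dashed line marks 5%. Telencephalic transcription factors reach 96.0%.

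The 5 strongest distal replicated peaks all overlapped noncoding genes. The highest signal value was 45.3, on chromosome 7 from 73555926 to 73558597, overlapping the noncoding gene 1810026B05Rik and 14096 bp from the nearest start of Chd2, a chromatin remodeller gene. Another, with a signal value of 40.3, lay on chromosome 13 from 83712884 to 83742927 and spanned 30044 bp, the widest of the replicated list. It contained Mir9-2, a gene of the neural microRNA miR-9, and overlapped the long noncoding RNA gene C130071C03Rik. Its width is that of the pooled call, and replicate 1 had several shorter peaks there. The widest peak of the single replicates' lists was 13259 bp in replicate 1 and 29145 bp in replicate 2. The peak on chromosome 7 from 79498844 to 79512278 (13435 bp, 34.4) contained Mir9-3. The others were at 2900052L18Rik on chromosome 11 (34.7) and at E230001N04Rik and Gm20109 on chromosome 17 (33.7).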

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

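For the peaks of 1 replicate only and for the abundant genes of other tissues, the tests were chosen after the values they rest on had been seen, and the strata for domains were added after the data were seen. The pooled list held 12693 peaks that overlapped neither replicate's own list, 21.7% of it. They were singled out as signal the report's main comparisons do not use, since all but 29 of them are outside the replicated list. A list called on more reads can hold weak peaks that the single lists lack, so their number by itself tests nothing. These peaks were weak, with a median signal value of 2.43, and 12.6% of them were at a TSS, against a mean of 4.42% for shifted peaks (permutation test, p = 0.001, the smallest possible). On sequences not placed on a chromosome, which the report leaves out, lay 10 replicated peaks, with a highest signal value of 11.5.

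Peaks called in 1 replicate only made up 41.1% of the replicate 1 list and 36.2% of the replicate 2 list. Calls spread at random over the genome do not account for all of them: 12.9% in replicate 1 and 15.2% in replicate 2 were at a TSS, above the highest of 1000 shifts of the same peaks (5.12% and 5.24%; permutation test, p = 0.001, the smallest possible). A relaxed threshold of the deposited lists stays open: of the peaks with a −log10 q of at least 5, 98.7% in replicate 1 and 97.5% in replicate 2 were overlapped by the other list, but 84.6% and 68.3% of these peaks were in signal ranges already seen to be shared, so the outcome was largely known. With that limit on both lists the shares were 93.4% and 86.0%. Differences between the pools of mice and in depth stay open too. The design has 1 group, so no biological explanation was tested.

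Of 1191 genes in the lists for liver, muscle, epidermis, lymphocytes, germline and olfactory receptors, 13 had a TSS peak. Of 12 abundant genes of those tissues (among them Alb, Afp, Acta1, Krt5, Cd3e and Ptprc), 0 had a TSS peak in any of the 4 lists. All 12 are members of these same gene lists and were picked after the 13 were known. Their outcome in the replicated list was therefore fixed, and cells of those tissues in the dissected samples stay open. The start of a neighbouring gene is a candidate explanation. The strongest peak lay also at another gene's start for 53.8% of the 13 (95% interval 29.1 to 76.8%), against 31.6% of the other genes with a TSS peak, a difference that was not past 0.05 (Fisher's exact test, p = 0.131); counting protein-coding neighbours only, a count added beside the set test, it was 46.2% against 20.7% (Fisher's exact test, p = 0.0353), so this stays open. Promoters active in brain cells themselves stay open, and no biological explanation was tested.

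Wide domains were found at 5 neural lists: telencephalic transcription factors, cortical excitatory neurons, GABAergic and striatal neurons, neuronal and synaptic genes, and neural progenitors. CpG content was not measured over the 10001 bp in which domains were scored, so CpG content over longer stretches stays open. At Nfib and Gad1, both among the widest, the TSS peak was not at the gene's 5′ end. For CpG content within 500 bp of that end, 5 of the 5 lists stayed past the threshold within 3 strata (conditional exact Mantel-Haenszel test, highest adjusted p = 0.00212). This argues against CpG content so measured as the whole cause. The same held for the number of annotated starts per gene (5 of 5, same exact test, highest adjusted p = 0.00360) and for the strength of the TSS peak (5 of 5, highest adjusted p = 0.00806). Over the other settings run, the highest adjusted p of these lists reached 0.137, at the gene's 5′ end alone, where 4 of the 5 stayed past it. Other technical causes were not tested, and with 1 tissue in the design no biological explanation was tested.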

How the results depend on the processing

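Of 307 alternative values for the 28 gene lists, 280 gave the same call, 16 lost it, 9 gained one and 2 turned direction; 15 lists kept their call throughout. For the other results, 58 of 88 values counted as the same and 30 as moved. Overlap shares and the share of peaks at a TSS counted as the same when the shift test kept its call, even where the value moved. The overlap share of replicate 1 went from 58.9% to 93.4% at a −log10 q of at least 5. The share of peaks at a TSS went from 59.6% to 35.1% with the pooled list. For named genes, 739 of 748 values counted as the same. The use of basic transcripts, leaving out starts near another gene, and the strata for domains were chosen after the data were seen. For every setting, the cause was not tested. Leaving out 1 replicate was not possible for overlap and rank correlation, which need both, and overlap of a peak's own length does not apply to the base overlap.

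Strata of promoter CpG content changed the call of 8 of the 28 lists. Of the 23 lists past the threshold, 16 stayed past it, and with the hypothalamic list 17 were past it. The erythroid list turned direction, to an odds ratio of 1.76. Calls were lost for GABAergic and striatal neurons (odds ratio 5.50), the cell cycle (1.93), microglia (0.0846), epidermal genes (0.163), lymphocyte genes (0.236) and immediate early genes (100% with a TSS peak, infinite odds ratio). The hypothalamic list became past the threshold (0.269).

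The choice of peak list changed the calls of several lists of brain regions and cell types. With the pooled list, the midbrain and hindbrain list turned direction (72.7%), meninges and choroid plexus (55.6%) and erythroid cells (43.8%) lost their call, and astrocytes gained one (93.8%). With 1 replicate left out, the midbrain and hindbrain list lost its call (50% without either replicate), as did meninges and choroid plexus without replicate 1 (55.6%). Hypothalamic genes gained a call without replicate 1 (38.9%) but not without replicate 2 (44.4%), and astrocytes without replicate 2 (93.8%). The share of all genes with a TSS peak was 64.8% without either replicate and 66.4% with the pooled list. The ratio of median signal values was 3.29 in the replicated list and 3.30 in the pooled list, and that of median widths 2.35 and 3.86.

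With a TSS window of 500 bp, myelinating oligodendrocytes (37.5%) and hypothalamic genes (33.3%) gained a call, the signal ratio was 3.09, the width ratio 4.00 and the share of peaks of 1 replicate only at a TSS 8.69%. With 2000 bp, 64.3% of genes had a TSS peak and these values were 2.09, 2.94 and 23.5%. With the gene's 5′ end alone, 59.8% of genes had one, imprinted genes lost their call (75%), hypothalamic genes gained one (33.3%), and the values were 3.22, 3.93 and 6.06%. With basic transcripts, 62.5% of genes had one, and the values were 3.06, 3.93 and 8.22%.

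Leaving out starts near another gene gave 55.3% of genes and a width ratio of 3.35. Calls were lost for meninges and choroid plexus (33.3%), erythroid cells (31.3%) and imprinted genes (68.2%). Without chemosensory receptors in the background, imprinted genes lost their call (87.5%) and hypothalamic genes gained one (38.9%).

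Peaks with a −log10 q of at least 5 gave a rho of 0.921, 62.5% of genes with a TSS peak, a signal ratio of 2.14, a width ratio of 1.85 and 28.8% of peaks of 1 replicate only at a TSS; hypothalamic genes gained a call (33.3%). Pairs of peaks with reciprocal overlap gave a rho of 0.941.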

Other observations

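The groups and genes in this section were chosen after the values had been seen. All 6 loci of the neural microRNAs miR-9 and miR-124a lay inside replicated peaks. The peaks holding Mir9-2, Mir9-1 and Mir9-3 were 30044, 18433 and 13435 bp wide, and those holding Mir124a-1, Mir124a-2 and Mir124a-3 were 10179, 4797 and 4714 bp wide. These are widths in the replicated list. No peak in the own list of replicate 1 was wider than 13259 bp, so none there spanned the Mir9 regions at these widths. Mir125b-1 lay in a peak of 11350 bp with a signal value of 30.7. Of 4586 lincRNA genes with every start over 5000 bp from a protein-coding start, 470 had a TSS peak (10.2%, 95% interval 9.40 to 11.2%). One of them was Malat1, with 24.4 ± 3.64 (SD, n = 2).

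Among gene families not in the fixed lists, a TSS peak was found at 78 of 78 mitochondrial ribosomal protein genes, 38 of 40 proteasome subunit genes, 22 of 22 genes of ephrins and their receptors, 18 of 20 semaphorin genes and 339 of 394 zinc finger genes named Zfp. It was found at 1 of 329 vomeronasal receptor genes, 0 of 42 beta-defensin genes, 4 of 53 keratin genes and 5 of 37 interleukin genes. Sox genes had one at 17 of 19, with a median covered length of 4449 bp. Some keratin genes, such as Krt1 and Krt10, and some Sox genes, such as Sox2 and Sox9, were also members of the fixed lists. On chromosome X, 444 of 948 genes had a TSS peak (46.8%), compared with 64.3% on the autosomes. Of the genes in the lowest, middle and highest of 3 strata of promoter CpG content, 14.5%, 78.3% and 97.7% had one.

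In the replicated list, the summit lay at a median of 133 bp downstream of the nearest start, and on the downstream side for 73.2% of TSS peaks. The 7966 replicated peaks over 5000 bp from any protein-coding start were nearest to 3918 genes. The 10 genes with the most were Zfp608 with 26, Gm26897 and Gse1 with 24 each, Gm11146 and Tcf4 with 22 each, Myt1l and Ttc28 with 21 each, Pou3f3 with 20, and Bcl11b and Sox4 with 19 each.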
